A study of Mus musculus with 12 samples.

How the data were processed

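Regulatory T cells from perigonadal white adipose tissue (PGWAT) and spleen of C57BL/6 mice on a high fat diet were measured on 12 Illumina MouseWG-6 arrays, 3 for each tissue in Foxp3Cre (control) and Tbet flox Foxp3Cre (Tbet flox) mice. Per the labels, RNA was isolated with Qiagen Allprep, 5 pg of total RNA (the unit as given there, which was not checked) was amplified with the NuGen Ovation Pico system and the cDNA was labelled with NuGen Encore Biotin IL kits. Per the labels, each tissue lay on 1 of 2 chips with 6 arrays each, with control arrays on the first and Tbet flox arrays on the last positions. Groups were taken from the titles and genotype labels.

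The deposited table of non-normalized signals holds 1 bead-averaged intensity per probe and array, per the file headers, with no background subtracted. The deposited table also holds a detection p-value per probe and array, per the file headers, which ranks the probe's signal among the array's negative control probes. Per the submitters' processing notes both were made with GenomeStudio, whose version was not stated. A table of processed values deposited by the authors holds intensities on a linear scale whose 12 columns share almost 1 distribution, so they were read as quantile normalized, and it was used for an alternative. Of 45281 probes, 34885 carried 1 gene symbol, 18 several and 10378 none. The symbols of 34807 probes were matched to the reference table by Entrez ID, which changed 0 symbols.

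Signals were background corrected and quantile normalized together with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16, a log2 scale and the background estimated from the detection p-values. Probes with a detection p-value under 0.05 on at least 3 arrays were kept (22833). The probe with the highest mean level stood for its gene, which left 15308 for testing, of which 10882 were named genes and 4426 probes without a name. Probes of a gene could disagree: of the called genes with several probes, 79 of 212 had a probe of opposite sign for genotype in PGWAT, 1 of 6 for the genotype effect between tissues, 198 of 882 between tissues in control and 97 of 527 in Tbet flox mice. Between 11252 and 17090 probes per array were detected at p under 0.01, and the highest correlation of any 2 arrays was 0.993. A linear model with 1 mean per group was fitted to all 12 arrays with limma (8 residual degrees of freedom, moderated, two-sided) and compared the genotypes in each tissue, the tissues in each genotype, and the genotype effect between tissues. P-values were adjusted by the method of Benjamini and Hochberg and the threshold was a limma adjusted p under 0.05. The same comparisons were fitted to the groups compared alone, with 4 residual degrees of freedom. Tbx21 and Foxp3 were also compared by exact permutation of 3 arrays against 3, which cannot go below 0.1.

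For each comparison the text names the 10 genes with the largest change past the threshold in each direction whose groups did not overlap and which were detected at p under 0.01 on all arrays of the brighter group, filled up to 5 by the smallest unadjusted p. It also names members of each list, up to 4 past the threshold or otherwise the 2 with the smallest p, and Tbx21 and Foxp3. Not all such members are printed, and genes named outside this rule are given as chosen after their values were seen. The 20 gene lists were written before the data were examined: Treg core, adipose Treg signature, T-bet and type 1 module, type 2 module, type 17 module, suppressor and checkpoint molecules, lymphoid homing and resting T cell genes, tissue homing receptors, cell cycle, interferon response, lipid metabolism, immediate early and stress genes, T cell identity, and markers of macrophages and monocytes, dendritic cells, B cells, CD8 and NK cells, adipocytes, stroma and endothelium, and red cells. Lists were tested with fry, whose p-value tests the balance of a list's members 1 way or the other and compares them with no other genes, and with camera, with a preset correlation of 0.01 and with an estimated one.

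The fit was tested on simulated data with 15308 genes, the spread of each tissue and 200 changed genes in each of 10 simulations. For genotype in PGWAT the fit of all arrays found 26.4% of changes of 1 log2 unit and 65.3% of changes of 2, with 213.8 false calls on average, and the fit of the PGWAT arrays alone found 0% with 0 false calls. For genotype in spleen the fit of all arrays found 10.7% and 58.8% with 0.3 false calls, and the fit of the spleen arrays alone 68.3% and 95.8% with 6.3. The fit of all arrays found 18.4% and 59% with 21.5 false calls for tissue in control mice, 17.4% and 59.6% with 25.1 for tissue in Tbet flox mice, and 1.7% and 30.7% with 11.6 for the genotype effect between tissues. In a test of the lists, 1 shifted list was found and 0 of 19 others were called.

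The fits, filters, lists and the following alternatives were chosen before the data were examined: quantile normalization with no background correction, median scaling, normalization per chip, the authors' processed values, no filter on dim probes, a stricter filter (detection p under 0.01 on all arrays of a group), the mean of a gene's probes, every probe on its own, the groups compared only, a trend of variance on level, array quality weights, the replicate number as a block, a log2 change of at least 1, and leaving out each array in turn. A weight per tissue, leaving out 2 doubted PGWAT arrays together and the macrophage score as a covariate were chosen after seeing the data. No array was left out of the comparisons given first. Probes without a gene name were counted but are not named, and raw scanner images were not used here.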

Results

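Regulatory T cells (Tregs) from mice on a high fat diet were profiled on 12 single-colour Illumina mouse expression arrays. Per the labels, the cells came from perigonadal white adipose tissue (PGWAT) or from spleen, and the mice were either Foxp3Cre controls or carried a floxed Tbet gene with Foxp3Cre. Foxp3Cre makes the Cre recombinase in cells that use the Foxp3 promoter, so the floxed mice were bred to lose T-bet in Tregs. T-bet is the transcription factor that drives type 1 T cell genes, and its gene symbol is Tbx21. The 4 groups held 3 arrays each. The questions were what the Tbet flox genotype changed in Tregs of each tissue, whether those changes differed between the tissues, and how adipose Tregs differed from spleen Tregs.

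Each array carried 45281 probes, of which 11252 to 17090 were detected at p under 0.01, and the median signal ran from 82.4 to 115. After the filter on dim probes, 15308 genes and unnamed probes were tested. The number of arrays limited the precision. The spleen arrays were close to each other, with correlations across genes of 0.978 to 0.984 among controls and 0.985 to 0.991 among Tbet flox arrays. The PGWAT arrays lay further apart, at 0.774 to 0.805 among controls and 0.824 to 0.872 among Tbet flox arrays. The median SD of a gene within a group was 0.552 log2 units in PGWAT control, 0.496 in PGWAT Tbet flox, 0.187 in spleen control and 0.15 in spleen Tbet flox. Per the labels, the arrays of each tissue lay on a chip of their own, so tissue and chip could not be told apart, and within each chip the genotypes held different positions. The p-values measure only the spread between these samples, since the labels do not say whether they came from separate animals.

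No difference in the target gene between genotypes was found in either tissue by its only probe. Levels are given as normalized log2 intensities, mean ± SD of 3 arrays. Tbx21 measured 5.66 ± 1.52 in PGWAT control and 5.95 ± 2.17 in PGWAT Tbet flox, a difference of 0.29 (exact two-sided permutation p = 0.9). In spleen it measured 5.26 ± 0.67 in control and 4.88 ± 0.15 in Tbet flox, a difference of -0.38 (exact two-sided permutation p = 0.5). The probe was dim, above background at p under 0.05 on only 1 of 3 arrays in PGWAT control and on 2 of 3 in each Tbet flox group, and the highest level of all 12 arrays, 8.45, was that of PGWAT Tbet flox 1. Leaving out PGWAT Tbet flox 1 turned the PGWAT difference to -0.96, leaving out PGWAT control 1 or 3 turned it to -0.23 or -0.06, and leaving out PGWAT control 2 raised it to 1.16. Leaving out spleen control 2 turned the spleen difference to 8.93e-05. With 3 arrays against 3, this test could not go below 0.1. Nothing in the files placed the probe inside or outside the floxed part of the gene, so its level checked neither the deletion nor the labels. Foxp3, the factor that defines Tregs, measured 7.54 ± 2.04 in PGWAT control and 8.36 ± 0.64 in PGWAT Tbet flox (exact p = 0.7). These are levels of the brightest of 3 kept probes, and in PGWAT the other 2 had differences of -0.25 and -0.83 (limma adjusted p = 0.622 and 0.395). In spleen Foxp3 measured 8.63 ± 0.26 in control and 8.54 ± 0.25 in Tbet flox (exact p = 0.6). Leaving out PGWAT control 1 turned the Foxp3 difference in PGWAT from 0.81 to -0.24, and leaving out spleen control 1 turned that in spleen from -0.09 to 0.05. Without control 1 and Tbet flox 3 together, 2 arrays doubted after the data were seen, the PGWAT difference was -0.42. By the brightest probe PGWAT control 1 had the lowest Foxp3 level of all 12 arrays, 5.44, so leaving it out was not independent of this difference. That array had the most detected probes of the PGWAT controls, 14753 at p under 0.01.

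**Figure D1:**
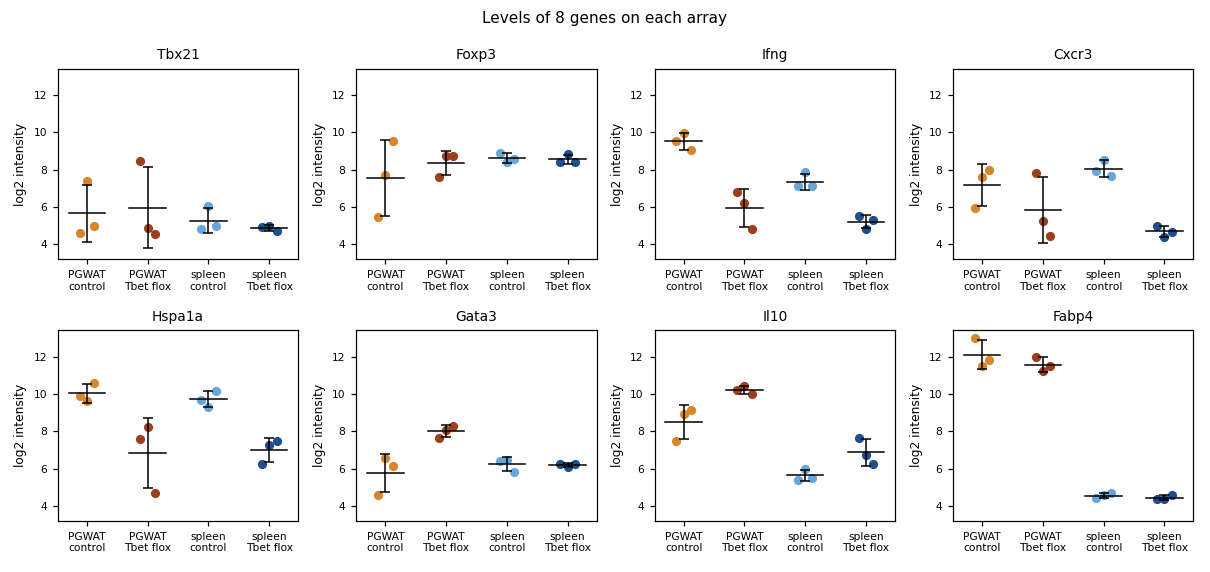
Normalized log2 intensity of 8 genes on each of the 12 arrays, by group, with 3 points per group, the mean as a line and the SD as a bar. Ifng lay at 9.50 ± 0.47 in PGWAT control and 5.95 ± 1.02 in PGWAT Tbet flox, and at 7.35 ± 0.43 and 5.22 ± 0.36 in the spleen groups, while Tbx21 varied within groups.

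In the PGWAT Treg samples, Ifng was lower and Gata3, Il5 and Ccr2 were higher in Tbet flox than in control by the fit of all 12 arrays. Macrophage markers measured lower and T cell genes higher on the same Tbet flox arrays, as given below. A change within Tregs therefore cannot be told apart from a change in RNA of other cells. Ifng, the hallmark cytokine of type 1 cells, was 9.50 ± 0.47 in PGWAT control and 5.95 ± 1.02 in Tbet flox, a change of -3.55 ± 0.47 log2 units (SE; limma adjusted p = 0.00453). Gata3, the factor that drives type 2 genes and supports Tregs in tissues, rose by 2.23 ± 0.43 (limma adjusted p = 0.0223), and the type 2 cytokine gene Il5 rose by 2.18 ± 0.51 (adjusted p = 0.0421). Ccr2, a receptor that brings cells to inflamed tissue, rose by 2.43 ± 0.47 (limma adjusted p = 0.022). Cxcr3, a receptor gene that T-bet switches on, measured 7.17 ± 1.10 in control and 5.83 ± 1.76 in Tbet flox and did not pass (limma adjusted p = 0.36); it was chosen after its values were seen, and without PGWAT Tbet flox 1 its adjusted p was 0.0415. None of these genes passed in the fit of the PGWAT arrays alone. With a weight for each tissue, chosen after seeing the data, none passed either, with limma adjusted p of 0.106 for Ifng, 0.248 for Gata3, 0.202 for Il5 and 0.242 for Ccr2.

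The largest measured rises in the PGWAT Tbet flox samples were those of Fam183b, a gene of ciliated cells, by 4.27 log2 units, and Mterf1a and Mterf1b, near-identical genes for a mitochondrial transcription factor, by 3.91 and 3.49. Where every probe of a gene was not above background on all arrays of the dimmer group, the fold was a bound, taken against the lowest signal called present on each of those arrays, or against the probe's own signal where that was higher. By that rule Fam183b rose at least 13.2-fold, Mterf1a at least 9.24-fold and St6galnac3 at least 4.87-fold. The probe used for Mterf1b was not above background on any PGWAT control array either, but another of its probes was on 1, so it has no bound and the size of its rise is not exact. Also among the 10 with the largest measured rise were Neb (3.16), Hsd17b7 of cholesterol synthesis (3.13), the chemokine gene Cxcl3 (3.02), the splicing gene Wbp4 (2.97), the calcium-signalling kinase gene Camk4 (2.85) and the mast cell protease gene Cpa3 (2.81). The limma adjusted p of these 10 genes lay between 1.03e-05 and 0.0497.

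After Ifng, the largest falls in PGWAT were of Hspa1a, an inducible heat shock gene (-3.18 log2 units), and of Il1a, an alarm cytokine gene (-3.13). Lamb2 (-2.95), Ccn1 (-2.94), Bcl6b (-2.91) and Aplnr (-2.81) fell. These are genes of matrix and vessel wall except for Bcl6b, a repressor gene found in lymphocytes and endothelium. Pogk fell (-2.87), as did Abca1, which exports cholesterol (-2.80). Ccl17, a chemokine gene of dendritic cells, was not above background on any Tbet flox array and fell at least 4.6-fold. Their limma adjusted p lay between 0.00344 and 0.0442. Leaving out 1 array ended the call of 12 of the 33 genes named as changed in PGWAT (2 of them, Hsph1 and Sox7, named in the closing section), and the value is given for 1 such array per gene. Without PGWAT control 1 the limma adjusted p was 0.0702 for Camk4, 0.0623 for Hspa1a, 0.0578 for Il1a and 0.0642 for Abca1. These genes also lost their call without any 1 of the spleen arrays, which do not enter the estimate of the change. Their calls therefore did not hang on 1 PGWAT array but lay close to the threshold.

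Some genes of Treg identity and suppression rose in the PGWAT Tbet flox samples, on arrays where all 16 macrophage markers measured lower (mean -1.75) and 10 of 11 T cell identity genes higher (mean 0.54). Of 16 measured Treg core genes, 3 rose, none fell and 13 did not pass, and 4 rose when adjusted over the list alone. They were Il2ra (1.28), the high-affinity IL-2 receptor chain, Ctla4 (1.15), a brake on T cell help, and Tnfrsf18 (1.48), a costimulatory receptor. The list did not pass as a whole (limma fry adjusted p = 0.0858). Of 14 suppressor and checkpoint genes, 2 rose, Fgl2 (2.03) and Ctla4, and 5 rose when adjusted over the list alone. That list moved up on balance by fry (limma adjusted p = 0.015) and also in the fit of the PGWAT arrays alone (0.0325), but its call by camera was lost at adjusted p = 0.533 with an estimated correlation. Of 18 genes of the adipose Treg signature, 4 rose, Ccr2, Gata3, Il5 and the differentiation marker Klrg1 (2.11), and 6 rose and 2 fell when adjusted over the list alone (limma fry adjusted p = 0.211). Of 8 type 2 genes, 3 rose, Gata3, Il5 and the interleukin receptor gene Il4ra (1.20), and 4 when adjusted over the list alone (limma fry adjusted p = 0.118). None of the genes named in this paragraph passed with a weight for each tissue, with limma adjusted p of 0.38 for Il2ra, 0.376 for Ctla4, 0.332 for Tnfrsf18, 0.518 for Fgl2, 0.492 for Klrg1 and 0.48 for Il4ra. Without PGWAT Tbet flox 3 the limma adjusted p was 0.0512 for Il2ra, 0.0601 for Ctla4 and 0.0557 for Gata3. Without PGWAT control 1 it was 0.0937 for Klrg1, 0.0808 for Tnfrsf18 and 0.0548 for Il4ra, and without PGWAT Tbet flox 2 it was 0.0891 for Il5. Klrg1, Tnfrsf18 and Il5 also lost their call without any 1 of the spleen arrays.

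Type 1 genes went both ways in PGWAT. Of 13 measured genes of the T-bet and type 1 module, Ifng and the chemokine gene Ccl3 (-2.63) fell and 11 did not pass, while 1 rose and 2 fell when adjusted over the list alone (limma fry adjusted p = 0.255). None of 16 cell cycle genes passed, and 1 rose when adjusted over the list alone. The replication genes Mcm6 and Mcm4 measured 1.01 and 1.17 higher with limma adjusted p of 0.0571 and 0.105, and without PGWAT control 3 Mcm4 passed at 0.0155 while Mcm6 passed without PGWAT control 2 at 0.0169. The cell cycle list moved up on balance by fry (limma adjusted p = 0.0137), but not in the fit of the PGWAT arrays alone (0.119), and had adjusted p = 0.533 with an estimated correlation by camera. Of 14 tissue homing receptors only Ccr2 passed, of 14 lipid genes only Abca1, and of 25 immediate early and stress genes only Hspa1a, with 2 falls among the stress genes when adjusted over the list alone. No member passed of the type 17 module (6 measured), the lymphoid homing and resting T cell genes (10), the interferon response (13) or T cell identity (11). Limma fry adjusted p for these 7 lists lay between 0.0858 and 0.893. The median and mean change differed in sign for the type 17 list (0.07 and -0.17) and the interferon list (-0.24 and 0.13).

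Markers of macrophages, dendritic cells, stroma and adipocytes measured lower on average in the Tbet flox PGWAT arrays, and those of B cells and of CD8 and NK cells measured higher. All 16 macrophage and monocyte markers measured lower, with a median change of -1.83, but only C1qa, a complement gene of tissue macrophages, passed (-2.67), and its call was lost with a weight for each tissue (limma adjusted p = 0.139). Much of this fall came from PGWAT Tbet flox 3, without which the median change was -0.90 and 14 of the 16 markers measured lower. Adjusted over the list alone, 11 fell. The list did not pass by fry (limma adjusted p = 0.101), and its call by camera with a preset correlation (4.06e-08) was lost at adjusted p = 0.533 with an estimated correlation. None of 8 dendritic cell markers passed, among them Cd74, which measured -1.52, and none of 11 stromal and endothelial markers, of which 10 measured lower, with Sparc at -1.38 (limma fry adjusted p = 0.255 and 0.375). Without PGWAT Tbet flox 1 Cd74 passed (limma adjusted p = 0.0457), and without PGWAT control 2 Sparc did (0.0278). No marker passed of B cells (4 measured), CD8 and NK cells (7), adipocytes (5) or red cells (3), and limma fry adjusted p for these 4 lists was 0.38 or higher. The red cell list had a median of -0.07 and a mean of 0.02. T cell genes measured higher in Tbet flox, with Zap70 at 1.29 and Cd4 at 1.23, and neither passed. Without PGWAT control 3, Zap70 passed at 0.0264, and without PGWAT Tbet flox 1, Cd4 passed at 0.0221.

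In all, 580 genes and unnamed probes changed in PGWAT by limma at an adjusted p under 0.05, 347 higher and 233 lower in Tbet flox, and 3100 had an unadjusted p under 0.05. When arrays were scaled to one median instead of quantile normalized, 110 were higher and 178 lower, and the median change of all genes moved from 0.04 to -0.08. The fit took 1 estimate of the spread from all 12 arrays, and the fit of the PGWAT arrays alone called 0, with a smallest limma adjusted p of 0.0533 and 1324 at an unadjusted p under 0.05. In 10 simulated data sets with the spread of each tissue and 200 changed genes each, the shared fit called on average 214 unchanged genes in this comparison, and the fit of the PGWAT arrays alone called 0 unchanged and 0 changed ones. With a weight for each tissue, chosen after seeing the data, 32 genes passed, and planned weights for each array also gave 32. Of the same 33 genes, 12 kept their call with the weight for each tissue, and these were Fam183b, Mterf1a, Mterf1b, Hsd17b7, Cxcl3, Wbp4, Cpa3, Lamb2, Ccn1, Bcl6b, Aplnr and Ccl3. The other 21 lost it. The arrays of the genotypes did not overlap for 14.5% of genes, against 10% by chance. Leaving out PGWAT control 2 raised the count to 1338 and leaving out PGWAT Tbet flox 1 to 896, and leaving out a spleen array lowered it to between 277 and 309. Without the 2 doubted PGWAT arrays, 1017 genes passed.

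**Figure D2:**
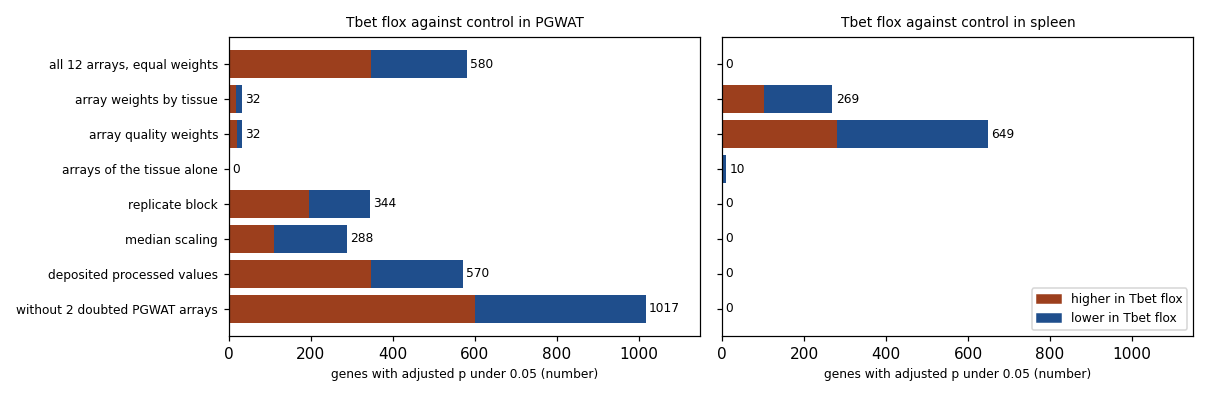
Number of genes with a limma adjusted p under 0.05 between Tbet flox and control, in PGWAT and in spleen, by the way the fit was made, with bars split into genes higher and lower in Tbet flox. With all 12 arrays at equal weight, 580 genes passed in PGWAT and 0 in spleen, and with a weight for each tissue 32 and 269 did.

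In spleen Tregs no gene passed by the fit of all 12 arrays, and the largest differences of named genes were lower levels of Cxcr3, Hspa1b, Hspa1a and Ifng. Cxcr3 measured 8.04 ± 0.45 in control and 4.69 ± 0.31 in Tbet flox, a difference of -3.35 ± 0.77 (SE) with limma adjusted p = 1. In the fit of the spleen arrays alone Cxcr3 fell (limma adjusted p = 0.00611), as did Ifng, from 7.35 ± 0.43 to 5.22 ± 0.36 (adjusted p = 0.0442), and Hspa1a, from 9.71 ± 0.44 to 6.99 ± 0.66 (adjusted p = 0.0442). Hspa1b, a near copy of Hspa1a, measured -2.79 and had the smallest limma adjusted p of the fit of all arrays (0.355); it did not pass in the fit of the spleen arrays alone (0.0637). With a weight for each tissue, chosen after seeing the data, Cxcr3 (0.000433), Ifng (0.00253), Hspa1a (0.00522) and Hspa1b (0.00253) fell, and Il10, an anti-inflammatory cytokine gene, rose from 5.64 ± 0.29 to 6.87 ± 0.72 (0.0468).

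The other genes that the fit of the spleen arrays alone called were chosen after their values were seen. Slfn9 rose by 1.82 log2 units (limma adjusted p = 0.022), Ccdc50 by 0.98 and Cyp4f16 by 1.00 (both 0.0442). Sntb2 (-1.08) and Czib (-0.98) fell (both 0.0442), Exoc8 fell (-0.95, 0.0499), and 1 unnamed probe fell. By the fit of all 12 arrays, the smallest unadjusted p among named genes that measured higher belonged to Cxcl2, a neutrophil chemokine gene (1.03), Nek4 (0.85), the DNA repair gene Apex1 (0.85), Thg1l (0.94) and Metap2 (0.96). Among those that measured lower, beside Hspa1b and Ifng, it belonged to Ly6k (-1.15), Crip2 (-1.09) and Pitpnm2 (-1.28). None of these 8 passed by that fit or by the fit of the spleen arrays alone. All 8 passed with a weight for each tissue, with limma adjusted p between 0.0115 and 0.0318, while Sntb2 (0.13) and Exoc8 (0.0829) did not.

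No member of any gene list passed in spleen by the fit of all 12 arrays, and no list passed by fry, whose smallest limma adjusted p was 0.188. Of 13 measured type 1 genes, 10 measured lower, and Ifng and Cxcr3 fell when adjusted over the list alone. Of 14 suppressor genes, 13 measured higher, led by Il10 (1.23) and Fgl2 (0.97), and of 16 Treg core genes 12 measured higher, with Tnfrsf18 at 0.68 and Il2ra at 0.61. Of 25 immediate early and stress genes 17 measured lower, and 1 fell when adjusted over the list alone. By camera with a preset correlation, limma's adjusted p was 0.000212 for type 1, 3.16e-06 for suppressor and 4.33e-07 for stress genes. These calls were lost, at limma adjusted p = 0.217, 0.15 and 0.153 with an estimated correlation. In the fit of the spleen arrays alone, by fry, the type 17 list moved up (limma adjusted p = 0.00548), with Il21 at 0.62 and Batf at 0.60, as did the cell cycle list (0.0434), with Top2a at 1.23 and Tyms at 0.73. By camera in that same fit both had limma adjusted p = 0.54 with an estimated correlation. Top2a rose with a weight for each tissue (limma adjusted p = 0.0279). Klf2, which keeps T cells circulating, measured -0.89 without passing. Adjusted over the list alone, 1 of 18 adipose Treg genes rose and 1 of 14 homing receptors fell. The other spleen lists had a limma fry adjusted p of 0.475 or higher. The median and mean differed in sign for homing receptors (0.19 and -0.12) and CD8 and NK markers (0.10 and -0.23). They also did for adipocyte markers (0.01 and -0.04) and stromal and endothelial markers (-0.000386 and 0.0432).

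Of the 16 macrophage and monocyte markers in spleen, 14 measured lower in Tbet flox, with a median change of -0.56 and with Cd163 at -1.35 and Lgals3 at -0.47. None passed. Of 7 CD8 and NK cell markers none passed, with Nkg7 at -1.68 and Prf1 at 0.17. With a weight for each tissue, Nkg7 fell (limma adjusted p = 0.0385).

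The count of 0 in spleen came from limma's fit of all 12 arrays, which had 284 genes at an unadjusted p under 0.05. The fit of the spleen arrays alone called 10 genes, 3 higher and 7 lower, with 2833 at an unadjusted p under 0.05. Planned weights for each array gave 649 genes, and a weight for each tissue gave 269, 103 higher and 166 lower. Groups did not overlap for 23.1% of genes, against 10% by chance. In the simulated data, the fit of all arrays found 10.7% of genes changed by 1 log2 unit in this comparison, and the fit of the spleen arrays alone found 68.3%.

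The genotype effect differed between the tissues for 18 genes and unnamed probes, 13 more positive in PGWAT and 5 more negative, and 14 of these had names. For 10 of these 14, the probe was not above background on any array of at least 1 group, so the size and order of their differences are not exact. Fam183b, above background on no control array of either tissue and on only 1 of 3 in spleen Tbet flox, had the largest measured difference, 3.99 ± 0.31 log2 units (SE; limma adjusted p = 0.000443), and measured 4.50 ± 0.18 in PGWAT control, 8.77 ± 0.30 in PGWAT Tbet flox, 4.43 ± 0.08 in spleen control and 4.71 ± 0.17 in spleen Tbet flox. Mterf1a (3.84) and its near copy Mterf1b (3.39) followed, and Mterf1a measured 4.34 ± 0.07 in PGWAT control, 8.26 ± 0.78 in PGWAT Tbet flox and 9.09 ± 0.23 in spleen control. The kinase gene Tnik (3.14), the glycosylation gene Galnt3 (2.76), Mmrn1 (2.65), the clock-related factor Hlf (2.63), the protease gene Mmp25 (2.20), Rab11fip1 (1.91) and Isy1 (1.79) had a more positive genotype effect in PGWAT. Pik3ap1, an adaptor of B cell and myeloid signalling (-2.70), Rxylt1 (-2.37), Fxyd2 (-2.20) and the endothelial factor Sox7 (-2.02) had a more negative one. Cfhr2 (-2.22) did not pass (limma adjusted p = 0.0529), and without PGWAT control 2 its adjusted p was 0.0165. The count moved with every array left out: it rose to between 52 (without Tbet flox 3) and 354 (without control 2) without any 1 of the PGWAT arrays, and fell to between 2 (without Tbet flox 3) and 5 without any 1 of the spleen arrays. Of the 14 named genes, only Fam183b kept its call with every array left out in turn. The simulations gave 11.6 false calls on average in this comparison, and the count fell with a replicate block, as given below.

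No type 1 gene passed for a difference between the tissues in its genotype effect. The difference was -1.42 for Ifng (limma adjusted p = 0.474), -2.63 for Ccl3 (0.0711) and 2.01 for Cxcr3 (0.532). Gata3 at 2.25 (0.19), Il13 at 1.35 (0.234) and the cytokine brake Socs1 at 1.69 (0.215) did not pass either. Of 8 type 2 genes, 4 had a more positive effect in PGWAT when adjusted over the list alone, and of 13 type 1 genes 1 had a more negative one. No list passed by fry, with a smallest limma adjusted p of 0.487, and the camera call of the macrophage markers with a preset correlation (0.000197) was lost at adjusted p = 0.785 with an estimated correlation. By limma 1681 genes had an unadjusted p under 0.05. Ccl3 passed without PGWAT control 2 (limma adjusted p = 0.0332), and so did Gata3 (0.0404). With median scaling, 6 genes were more positive and 5 more negative, and the median difference of all genes moved from 0.05 to -0.07. The interferon list had a median of -0.10 and a mean of 0.13, and the lipid list 0.00334 and -0.176.

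In control mice, genes of lipid handling measured higher in the PGWAT samples than in the spleen samples, and several lymphoid genes measured lower. Fabp4, a fatty acid carrier, measured 12.10 ± 0.79 in PGWAT and was not above background in spleen, a rise of at least 158-fold (limma adjusted p = 6.84e-07). Cd36, a fatty acid transporter, rose by 6.43 ± 0.30 log2 units (SE), and Pparg, the lipid-sensing factor that shapes adipose Tregs, rose from 4.78 ± 0.17 to 7.18 ± 0.46 (limma adjusted p = 0.000466). Il10 rose from 5.64 ± 0.29 to 8.51 ± 0.92 (limma adjusted p = 0.00217). Ifng was also higher in PGWAT, by 2.15 (limma adjusted p = 0.0112), and without spleen control 1 its adjusted p was 0.0518.

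The largest rises in PGWAT of control mice also included the water channel gene Aqp1, at least 125-fold, and the chemokine genes Cxcl1, at least 107-fold, Ccl7 (7.09 log2 units), Cxcl2 (6.43) and Pf4, at least 77.8-fold. Dab2 rose at least 92.6-fold, Retnla at least 70.9-fold and the matrix gene Sparc at least 73.9-fold. All 10 had a limma adjusted p of 0.000144 or less. The largest falls were of Mterf1a, at least 16.5-fold, Mterf1b (-4.54 log2 units), the Notch regulator Dtx1, at least 10.9-fold, and Lta, which builds lymphoid tissue (-3.83). Ces2d-ps (-3.67), Zfp827 (-3.66), Ifit1bl1 (-3.62), Ilvbl (-3.59) and the cell cycle factor E2f2 (-3.43) also fell, and Tesc fell at least 7.52-fold. Ilvbl had a limma adjusted p of 0.0304, and 0.0802 without PGWAT control 3. The probes used for Ccl7 in spleen and for Mterf1b in PGWAT were not above background on any control array, but another probe of each was, so these 2 sizes are not exact.

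By list, the adipose Treg signature was higher in PGWAT of control mice, with 9 of 18 measured genes up, none down and 12 up when adjusted over the list alone. Its fry adjusted p was 9.14e-05 by limma and its camera call was lost at adjusted p = 0.113 with an estimated correlation. Beside Cxcl2, Cd36 and Pparg, it held Ccl6, at least 5.79-fold higher. On the same arrays 14 of 16 macrophage and 6 of 11 stromal markers also rose. A rise of the signature within Tregs therefore cannot be told apart from RNA of other cells. Of 14 lipid genes 7 rose, among them Scd1 (at least 14.4-fold), which makes unsaturated fats, and Lpl (4.44), which frees fatty acids, and 7 rose when adjusted over the list alone. The lipid list passed by fry (3.85e-06) and kept its camera call with an estimated correlation (0.00851), though not in the fit of the control groups alone (limma adjusted p = 0.1). Of 25 immediate early and stress genes 17 rose and 1 fell, with Atf3 (at least 29.9-fold), Ier3 (5.51), Nr4a2 (3.80) and Fosb (3.07), and 17 rose and 2 fell when adjusted over the list alone. That list passed by fry (8.96e-06), with limma adjusted p = 0.0927 with an estimated correlation by camera. Of 14 suppressor genes 4 rose, with Il10 and Fgl2 (1.69), and Nt5e fell (-2.36), with the same numbers adjusted over the list alone (fry 0.00547; limma adjusted p = 0.185 with an estimated correlation). Of 13 type 1 genes Ccl3 (at least 8.86-fold), Ifng and Ccl4 (3.15) rose, and 4 rose when adjusted over the list alone (fry 0.0218; limma adjusted p = 0.249 with an estimated correlation). Without spleen control 1 the limma adjusted p of Fgl2 was 0.0559, and without PGWAT control 1 that of Ccl4 was 0.062.

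Lymphoid and T cell genes were lower in PGWAT of control mice. Of 10 lymphoid homing and resting T cell genes 3 fell, the T cell factor gene Lef1 (-2.37), the survival gene Bcl2 (-2.03) and the chromatin organiser gene Satb1 (-1.15), also when adjusted over the list alone (limma fry adjusted p = 0.00289; adjusted p = 0.232 with an estimated correlation). Of 11 T cell identity genes 4 fell, Cd247 (-2.00), Zap70 (-1.85), Cd5 (-1.69) and Cd3d (-0.82), and 8 fell when adjusted over the list alone (fry 0.00287; limma adjusted p = 0.232 with an estimated correlation). Of 16 cell cycle genes Mcm6 (-1.48), Mcm7 (-2.06) and Mcm4 (-1.41) fell, also when adjusted over the list alone (fry 0.000912; limma adjusted p = 0.196 with an estimated correlation). Of 16 Treg core genes Swap70 rose (2.16) and Gpr83 (at least 5.44-fold), Nt5e and Izumo1r (-2.57) fell (fry 0.149). Among 14 homing receptors Cxcr4 rose (2.07) and Itgae, an integrin gene of cells in epithelium, fell (-2.42; fry 0.365). Ifit3 (-1.97) and Ifit2 (-2.24) fell among 13 interferon genes (fry 0.062), Rora rose among 6 type 17 genes (1.24; fry 0.317), and none of 8 type 2 genes passed (fry 0.317). In these 5 lists the counts adjusted over the list alone were equal to those over all genes. Without PGWAT control 1 the limma adjusted p of Bcl2 was 0.0525, of Cd3d 0.0987 and of Mcm4 0.0667. Without PGWAT control 3 that of Satb1 was 0.0614 and that of Ifit2 0.0556. Without spleen control 1 that of Mcm7 was 0.0635, that of Cd5 0.0528 and that of Rora 0.057.

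Markers of macrophages, dendritic cells and stroma rose beside these genes in PGWAT of control mice. Of 16 macrophage and monocyte markers 14 rose, with the lysozyme genes Lyz1 (4.21) and Lyz2 (4.08), C1qa (3.73) and Lgals3 (3.47), and 15 rose when adjusted over the list alone. Of 8 dendritic cell markers 4 rose, among them H2-Aa (2.97) and Cd74 (3.54) of antigen presentation, and Cd74 measured 12.43 ± 0.08. Of 11 stromal and endothelial markers 6 rose, with Sparc, Dcn (at least 22.5-fold) and Col1a2 (at least 18.3-fold), and 9 when adjusted over the list alone. Of 5 adipocyte markers only Fabp4 rose, and 3 rose and 1 fell when adjusted over the list alone. Of 4 B cell markers Cd79b fell (-1.31; limma adjusted p = 0.0447, and 0.0565 without PGWAT control 2), and none of 7 CD8 and NK cell or 3 red cell markers passed. Adjusted over the list alone, 1 B cell marker rose and 1 fell. Limma fry adjusted p was 0.886 for the B cell, 0.747 for the CD8 and NK cell and 0.317 for the red cell list. The median and mean differed in sign for the B cell (0.09 and -0.04) and the CD8 and NK cell list (-0.05 and 0.15). By limma fry the macrophage, dendritic cell, stromal and adipocyte lists moved up, with adjusted p of 0.00216, 0.00286, 0.000699 and 0.000197. All 4 had limma adjusted p = 0.18 with an estimated correlation by camera.

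**Figure D3:**
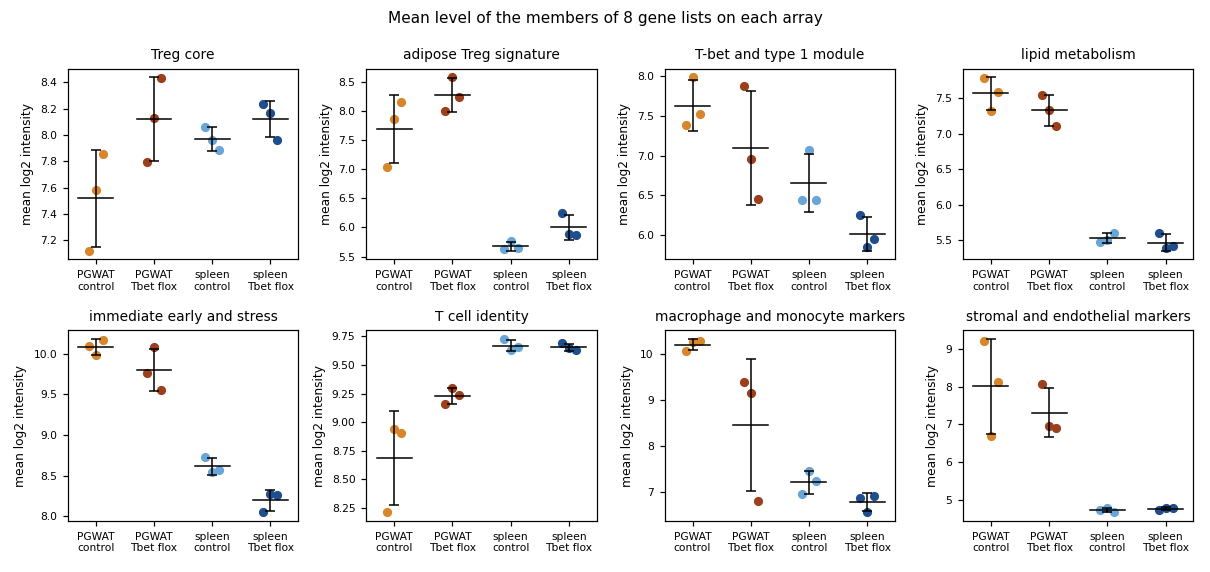
Mean log2 intensity over the measured members of 8 gene lists on each of the 12 arrays, by group, with 3 points per group, the mean as a line and the SD as a bar. The axes of the panels differ. The macrophage and stromal markers and the adipose Treg signature lay higher in PGWAT than in spleen, and the PGWAT arrays of a group lay further apart than the spleen arrays.

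In Tbet flox mice, genes of lipid handling and type 2 genes were among those that rose in PGWAT. Fabp4 rose at least 112-fold, Aqp1 at least 72.1-fold and Cd36 at least 65.7-fold. Il10 rose from 6.87 ± 0.72 to 10.20 ± 0.21 (limma adjusted p = 0.00127), Ctla4 by 1.25 (0.00942) and Pparg by 2.84 (0.000211). Of 8 type 2 genes 4 rose, Il5, Il13, Il4ra and Gata3, at least 9.52-fold for Il5 and by 1.69, 1.11 and 1.79 log2 units for the others, and 5 when adjusted over the list alone (limma fry adjusted p = 0.0131; adjusted p = 0.266 with an estimated correlation). Without spleen Tbet flox 3 the limma adjusted p was 0.0518 for Ctla4 and 0.103 for Il4ra, and without PGWAT Tbet flox 2 that of Gata3 was 0.0513.

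The other large rises in Tbet flox mice were of the nuclear lamina gene Lmna (6.20 log2 units), the AP-1 gene Fosl2 (5.77), the lectin gene Clec10a (5.46), Ccl7 (5.65) and Cxcl2 (5.35), with Dab2 at least 40.8-fold and Cxcl1 at least 33-fold. The largest falls were of the interferon-related gene Ifit1bl1 (-4.91), Ces2d-ps (-4.15), Lta (-4.09) and the iron exporter gene Slc40a1 (-4.03). The innate sensor gene Nod1 (-3.74), Ift80 (-3.69), Card6 (-3.68), Ifit2 (-3.48) and Mrps35 (-3.38) also fell, and Dtx1 fell at least 7.5-fold. The limma adjusted p of these falls was 0.00706 or less. The size for Ccl7 is again not exact, by the same probe in spleen.

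By list, 13 of 18 adipose Treg genes rose in PGWAT of Tbet flox mice, with Dgat1 (3.89) of fat storage among them, and 14 rose and 1 fell when adjusted over the list alone (limma fry adjusted p = 5.26e-05; adjusted p = 0.057 with an estimated correlation). Some macrophage and stromal markers rose there too, so a rise within Tregs cannot be told apart from RNA of other cells. Of 14 lipid genes 7 rose, with Scd1 at least 11.2-fold higher, and 8 when adjusted over the list alone (fry 8.83e-06, and 0.0134 by camera with an estimated correlation; limma adjusted p = 0.221 in the fit of the Tbet flox groups alone). Of 25 immediate early and stress genes 14 rose and 1 fell, with Atf3 (at least 24.2-fold), Ier3 (5.12), Nr4a2 (3.84) and Fosb (3.59), and 16 rose and 1 fell when adjusted over the list alone (fry 1.15e-05; limma adjusted p = 0.057 with an estimated correlation). Of 14 suppressor genes 7 rose, with Fgl2 (2.75) and Il10ra (1.26), and 1 fell, and 8 rose and 1 fell when adjusted over the list alone (fry 0.00119; limma adjusted p = 0.177 with an estimated correlation). Among 13 type 1 genes Xcl1 (2.49) and Gzmb (2.38) rose, by all genes and by the list alone (fry 0.0202; limma adjusted p = 0.237 with an estimated correlation). Of 14 homing receptors Cxcr4 (2.19) and Ccr2 (2.92) rose and Ccr6 fell (-1.67), while 5 rose and 1 fell when adjusted over the list alone (fry 0.0131; limma adjusted p = 0.266 with an estimated correlation). Without PGWAT Tbet flox 1 the limma adjusted p of Gzmb was 0.0513, without PGWAT Tbet flox 3 that of Ccr6 was 0.0945, and without spleen Tbet flox 3 that of Il10ra was 0.0786.

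Of 10 lymphoid homing and resting T cell genes 4 fell in PGWAT of Tbet flox mice, Satb1 (-1.59), Bcl2 (-2.63), Lef1 (-1.35) and the lymph node homing receptor gene Ccr7 (-1.82), while 1 rose and 4 fell when adjusted over the list alone (limma fry adjusted p = 0.0121; adjusted p = 0.295 with an estimated correlation). Of 11 T cell identity genes Cd28 rose (1.09) and Cd5 fell (-2.29), and 1 rose and 2 fell when adjusted over the list alone (fry 0.186). Of 16 Treg core genes 2 rose, Swap70 (2.18) and Ctla4, and 3 fell, among them Gpr83 (-2.66) and Nt5e (-1.63), by all genes and by the list alone (fry 0.849). That list had a median of 0.125 and a mean of -0.00159. None of 16 cell cycle genes passed, with Mcm7 at -1.58, and the list moved down by fry (0.0164), with limma adjusted p = 0.345 with an estimated correlation. Of 13 interferon genes Cxcl10 rose (2.42) and Ifit2 and Ifit3 fell, and 3 fell when adjusted over the list alone (fry 0.113). Of 6 type 17 genes Rora rose (1.44) and Il21 and Ccr6 fell, Il21 at least 1.3-fold, and 3 fell when adjusted over the list alone (fry 0.0574). Without PGWAT Tbet flox 1 the limma adjusted p of Ccr7 was 0.0529 and that of Cxcl10 0.0624. Without PGWAT Tbet flox 3 that of Il21 was 0.0503, and Mcm7 passed at 0.00627 without PGWAT control 1. Without spleen Tbet flox 2 that of Lef1 was 0.0686 and that of Cd28 0.064, and without spleen Tbet flox 1 that of Nt5e was 0.0753.

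Markers of macrophages, dendritic cells and stroma measured higher in PGWAT than in spleen in Tbet flox mice. Of 16 macrophage and monocyte markers 4 rose, Lgals3 (3.88), Lyz2 (2.63), Lyz1 (2.47) and Fcer1g (1.94), and 10 rose when adjusted over the list alone. Of 8 dendritic cell markers 4 rose, with H2-Aa at 2.62 and Cd74 at 2.43, and of 11 stromal and endothelial markers 5 rose, with Col1a2 at least 12.9-fold, Sparc at least 29.1-fold and Dcn at least 22.9-fold higher, each by all genes and by the list alone. Of 5 adipocyte markers only Fabp4 rose, and none of 4 B cell, 7 CD8 and NK cell or 3 red cell markers passed (limma fry adjusted p = 0.701, 0.0718 and 0.113). By limma fry the macrophage, dendritic cell, stromal and adipocyte lists moved up, with adjusted p of 0.0273, 0.0131, 0.00296 and 0.000329. By camera these had limma adjusted p = 0.284 for the macrophage list and 0.237 for the others with an estimated correlation. In the fit of the Tbet flox groups alone the macrophage list did not pass by fry (limma adjusted p = 0.107). In that fit the CD8 and NK cell (0.00693), T cell identity (0.00172) and type 17 (0.0466) lists passed by fry. By camera in that fit, with an estimated correlation, none of these lists passed. Fcer1g had a limma adjusted p of 0.0498 over all genes, and 0.131 without PGWAT Tbet flox 1. Without spleen Tbet flox 3 that of Lyz1 was 0.0546 and that of Lyz2 0.0533.

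Between the tissues, 2417 genes passed by limma in control mice, 915 higher and 1502 lower in PGWAT, and 1549 passed in Tbet flox mice, 697 higher and 852 lower. Of these, 378 were higher in both genotypes, against 41.7 for independent lists, and 458 were lower in both, against 83.6. The fit of the groups compared alone called 1728 and 1771 genes. With median scaling, 22.4% of the genes called in Tbet flox mice were higher in PGWAT, against 45% with quantile normalization, and the median difference of all genes moved from -0.12 to -0.22 in control and from -0.04 to -0.28 in Tbet flox mice. Without the 2 doubted PGWAT arrays 2362 genes passed in Tbet flox mice. Leaving out any 1 of the spleen control arrays lowered the count in control mice to between 1196 and 1350, and leaving out any 1 of the spleen Tbet flox arrays lowered that in Tbet flox mice to between 617 and 660. Of the genes named as called, 13 of 61 in control and 15 of 62 in Tbet flox mice lost their call with at least 1 array left out. Since each tissue had its own chip, these differences hold any difference between the chips as well.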

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

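The splits of the arrays were planned, while the tests of spread, array quality, marker correlation, chips, CD8 and NK markers and positions were chosen after the result was seen. The genotype effect differed between PGWAT and spleen, by the test of the difference itself, for 14 named genes. The difference in log2 units was 3.99 for Fam183b, 3.84 for Mterf1a, 3.39 for Mterf1b, 3.14 for Tnik, 2.76 for Galnt3, 2.65 for Mmrn1, 2.63 for Hlf, 2.20 for Mmp25, 1.91 for Rab11fip1, 1.79 for Isy1, -2.02 for Sox7, -2.20 for Fxyd2, -2.37 for Rxylt1 and -2.70 for Pik3ap1. For 10 of the 14, all but Tnik, Mmrn1, Isy1 and Rxylt1, the probe was not above background on any array of at least 1 group, so these sizes and their order are not exact. With the genotype labels exchanged within tissues, 3 of 100 relabellings, the real one included, gave at least as many genes as the real 18. The highest other gave 39, which is also the count for the genotype effect averaged over tissues. Such relabelling tests for no genotype effect at all, so it cannot decide whether the effect differed between tissues. The simulations gave 11.6 false calls on average in this comparison, and 1 of the 14 genes kept its call with every array left out in turn.

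Between genotypes, 580 genes passed in PGWAT by the limma fit of all arrays and 0 by the fit of the PGWAT arrays alone, which had 1324 at an unadjusted p under 0.05. Of the 10 splits of the 6 arrays, 1 (the real one) gave as many, and the highest other gave 223. The splits were too few for a share under 0.05. Whether each PGWAT group held a poor array was not decided. The highest correlation of 2 arrays of the same PGWAT group was 0.872, below the lowest of the spleen groups, 0.978. The comparison takes for granted that good PGWAT arrays would be as close as spleen arrays. PGWAT Tbet flox 3 had the fewest detected probes at p under 0.01 (11252), but not at p under 0.05. There it had 17169, more than PGWAT control 1, 2 and 3 (16902, 16982 and 15274) and Tbet flox 1 (15668). Its macrophage score was 6.81, against 9.40 and 9.16 for Tbet flox 1 and 2. The spread shared with the tighter spleen arrays made false calls in the simulations, 213.8 on average. With a weight per tissue 32 genes passed. Both argue that the count of 580 is too high. The fit with a weight per tissue was chosen after seeing the data and was not simulated, so its false calls are not known. A biological effect of genotype stays open for those 32, and the loss of a call there does not exclude one for other genes. In spleen the splits decided nothing, since every split reaches the real count of 0 (limma, 284 at an unadjusted p under 0.05), here 10 of 10 with 0 as the highest other.

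Markers of macrophages, dendritic cells and stroma were high in the PGWAT samples, with Cd74 at 12.43 ± 0.08 and Lyz2 at 11.97 ± 0.06 in PGWAT control. Over the PGWAT arrays the 16 macrophage markers had a mean pairwise correlation of 0.879 after group means were removed, against 0.122 for the 95th percentile of random lists. Without PGWAT Tbet flox 3 the correlation was 0.123 against 0.147, so it rested on 1 array. The 11 stromal and endothelial markers had a correlation of 0.595 against 0.144 for random lists, not repeated with arrays left out. Their mean level was 9.19, 6.70 and 8.13 on PGWAT control 1, 2 and 3. These correlations concern variation between arrays, and not whether RNA of other adipose cells was present. Such RNA stays open as a candidate source of the high levels. A difference between the chips cannot be told apart from tissue, because 0 chips hold both tissues. A smaller share of all other cells alike in Tbet flox PGWAT stayed undecided, with a change of the macrophage minus the stromal score of -1.06 and an SE of 1.03. Between tissues 1 of 10 splits, the real one, gave as many genes in control mice (2417, highest other 0) and 1 of 10 in Tbet flox mice (1549, highest other 0), and these splits were too few for a share under 0.05.

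Ifng measured lower in Tbet flox in both tissues. It was called by the limma fit of all arrays in PGWAT and by the fit of the spleen arrays alone in spleen. None of the fits of all arrays, of 1 tissue alone or with a weight per tissue called it in both. A fall of all CD8 and NK cells alike was argued against as the whole cause. Their 7 markers had a median change of 0.17 in PGWAT (SD between markers 0.764) against -3.55 for Ifng. In spleen it was 0.10 (SD between markers 0.676) against -2.13. This SD is not the error of the median, which a fall of only some of these cells could leave unmoved. In spleen the mean of the markers was -0.23. The marker Nkg7 measured -1.68 there and passed with a weight per tissue (limma adjusted p = 0.0385), so a change in some of these cells stays open. The position on the chip cannot be told apart from genotype, because 0 chip positions hold both genotypes. A direct effect of losing T-bet on Ifng stays open as a hypothesis, and with a weight per tissue the limma adjusted p of Ifng was 0.106 in PGWAT and 0.00253 in spleen.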

How the results depend on the processing

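The fits with a weight per tissue, without 2 doubted arrays (PGWAT control 1 and Tbet flox 3) and with the macrophage score as a covariate were chosen after the result was seen, and the others before the data were examined. The count of 580 genes by genotype in PGWAT was 288 with median scaling, 0 with the groups compared only (limma, 1324 at an unadjusted p under 0.05), 32 with array quality weights, 344 with the replicate block, 32 with a weight per tissue, 1017 without the doubted arrays and 173 with the macrophage covariate, and 277 to 1338 with 1 array left out. The count of 0 in spleen (limma, 284 at an unadjusted p under 0.05) was 10 with the groups compared only, 649 with array quality weights and 269 with a weight per tissue, and 0 to 0 with 1 array left out. The 18 genes whose genotype effect differed between tissues were 41 with quantile normalization and no background correction, 11 with median scaling, 41 with the authors' processed values, 39 with no filter on dim probes, 29 with the stricter filter, 11 with a variance trend, 3 with the replicate block, 0 with the replicate block within genotype (limma, 1405 at an unadjusted p under 0.05), 11 with a weight per tissue and 241 without the doubted arrays, and 2 to 354 with 1 array left out. Between tissues the count of 2417 in control mice was 1481 with the replicate block within genotype and 1196 to 3138 with 1 array left out. In Tbet flox mice the count of 1549 was 709 with that block, 2362 without the doubted arrays and 617 to 2202 with 1 array left out.

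The Tbx21 difference in PGWAT (0.29) was -0.18 with array quality weights, 2.05 with the macrophage covariate and -0.96 to 1.16 with 1 array left out, and that in spleen (-0.38) was 0.0548 with the macrophage covariate and -0.61 to 8.93e-05 with 1 array left out. The Foxp3 difference in PGWAT was -0.0904 with the mean of its probes, -0.42 without the doubted arrays and -0.24 (without control 1) to 1.79 with 1 array left out, and in spleen it was -0.23 to 0.053 (without control 1). The Cxcr3 difference in PGWAT was 0.36 with the macrophage covariate. Mean list changes turned in these cases. With median scaling the interferon list in PGWAT was -0.0135 and the red cell list -0.204, the latter being -0.0156 with quantile normalization and -0.0146 with the authors' values. The interferon list in spleen was 0.0334, 0.0023 and 0.0332 with quantile normalization, median scaling and the authors' values. Between the tissues' genotype effects, median scaling gave -0.0204 for the T-bet list, -0.149 for resting T cell, -0.115 for cell cycle, -0.0158 for interferon and -0.0683 for stress genes. Between tissues in control mice the B cell list was 0.0188 with quantile normalization and 0.0179 with the authors' values. In Tbet flox mice the Treg core list was 0.0903 and 0.0888 with these, and the B cell list was -0.0527 with median scaling. Over all alternatives, 134 results of the comparisons were the same, 49 moved and 6 reversed. For named genes 5331 were the same, 545 weaker, 101 stronger and 5 reversed, and for lists 525, 42, 16 and 17.

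The data did not show that the replicate numbers paired the arrays. This check could not exclude a pairing, since the PGWAT arrays varied widely within groups and the labels do not name the animals. Correlations of the deviations of arrays with the same number were -0.199 to 0.0757, and in 3 of 12 comparisons an array had its best partner at its own number. Signals near background limit what dim genes can show, since the deposited signals carry no control probes. With 1 spleen array left out, genotype estimates in PGWAT stayed the same (Camk4 at 2.85) while the count fell to 277 to 309, so the spread and degrees of freedom shared between tissues moved it. For the other moved and reversed results the cause was not tested.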

Other observations

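The genes in this part, its average over tissues and its groupings were chosen after the result was seen. Some inducible heat shock genes measured lower in the Tbet flox samples. Hspa1a measured 10.03 ± 0.50 in PGWAT control and 6.84 ± 1.89 in PGWAT Tbet flox, and 9.71 ± 0.44 and 6.99 ± 0.66 in the spleen groups. Hspa1b, its near copy, measured -1.53 in PGWAT (limma adjusted p = 0.0608) and -2.79 in spleen (0.355). Hsph1, a partner chaperone, fell in PGWAT (-1.44, limma adjusted p = 0.0477) and measured -0.32 in spleen. Dnajb1, which works with these chaperones, measured -0.88 and -0.43 and did not pass. With a weight per tissue neither Hsph1 (limma adjusted p = 0.477) nor Dnajb1 (0.107) passed in spleen, and in PGWAT Hspa1a (0.325), Hspa1b (0.688), Hsph1 (0.516) and Dnajb1 (0.514) did not pass. Without spleen Tbet flox 1 Hspa1b passed in PGWAT (0.0471), without PGWAT Tbet flox 2 Dnajb1 did (0.0321), and without PGWAT control 3 Hsph1 did not (0.0854).

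A few single genes of vessel walls and mast cells passed in PGWAT, while others did not, and no list of mast cell genes was tested. Sox7, an endothelial factor, fell from 6.45 ± 0.32 to 4.53 ± 0.20, with its probe not above background on any Tbet flox array, beside Aplnr and Lamb2, while the endothelial junction genes Esam (-1.89, limma adjusted p = 0.0568) and Cldn5 (-1.13, 0.215) did not pass. With a weight per tissue Sox7 did not pass (limma adjusted p = 0.0785). Esam passed without PGWAT control 3 (0.0211). The mast cell gene Cpa3 rose from 4.93 ± 0.83 to 7.74 ± 0.76, and Cma1, a mast cell chymase gene, measured 1.36 without passing (limma adjusted p = 0.192), and passed only without PGWAT Tbet flox 3 among the single arrays left out (0.00619).

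Averaged over both tissues, 39 genes and unnamed probes had a genotype effect past the threshold by limma, 22 higher and 17 lower in Tbet flox, with 8 unnamed. They include genes that changed mainly in PGWAT, such as Fam183b, with an average of 2.28 from 4.27 in PGWAT and 0.29 in spleen. Mterf1a, Mterf1b, Tnik, Hlf and Pik3ap1 are others, so the count is not one of effects common to both tissues. Ifng had an average effect of -2.84 (limma adjusted p = 0.0097), Hspa1b -2.16 (0.015), and the suppressor gene Fgl2 rose (0.0495). Acot11, a thioesterase gene of fatty acid metabolism, rose by 1.57 and Exosc9, an RNA exosome gene, by 1.27. This fit shares its spread between tissues as the other fits do. Across all genes, the genotype effects in PGWAT and spleen had a correlation of 0.0113. The median SD within a PGWAT group, 0.552 in control and 0.496 in Tbet flox, was large beside the median absolute genotype effect in spleen, 0.171. Such spread can lower this correlation, so it does not show that the effects were unrelated. The tissue differences in control and Tbet flox mice had a correlation of 0.657. They share any difference between the chips, so these correlations cannot be compared. Of the genes called between tissues in both genotypes, 5 had opposite directions.

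As a hypothesis, Ifng, Hspa1a and Hspa1b may depend on T-bet in Tregs of both tissues. A fit with a weight per tissue called these 3 genes in spleen (269 genes in all) and none of them in PGWAT (32 genes in all). Another hypothesis is that a share of the RNA of the PGWAT samples came from other adipose cells, whose markers were high there. The correlation of 0.879 among macrophage markers rested on 1 array, and it concerned variation between arrays rather than presence. Stricter sorting would remove such cells, and the labels give no purity. Profiling both tissues on each chip, with genotypes spread over positions, would separate chip from tissue and position from genotype.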
